A study of Mus musculus with 2 samples.

How the data were processed

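Gene expression was measured in single mouse CD8+ T cells of lymph node origin with the 10x Genomics 3' v3.1 kit, per the submitters' records, in 1 library labelled NC and 1 labelled HC. That kit tags each captured RNA molecule at its 3' end with a cell barcode and a unique molecular identifier (UMI). The deposited files hold UMI counts per gene and barcode, not normalized, with 32285 genes in each library. Cell Ranger 6.1.2 made the matrices, per the file headers, while the submitters' processing notes name Cell Ranger 5.0.0, Seurat 3.2.3 and the build mm10, with no role or order. The annotation release and the rule by which barcodes were kept are not given in the sources used here. No barcode in the files had fewer than 500 UMIs.

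Kept cells had at least 500 detected genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrially encoded genes, with no upper limit. Scrublet was run on each library through scanpy, but its automatic threshold called 0 cells and thus has not worked, so doublets were not removed. Counts were summed over the kept cells of each library and divided by the library's total to give CPM (UMIs per 1000000 UMIs). Cells are not replicates and there was 1 library per group, so no test was run and no p-value is given. CPM carry exact Poisson intervals, shares of cells exact binomial (Clopper-Pearson) intervals, and log2 ratios of HC over NC exact binomial intervals, all at 95% and for counting error only. No pseudocount was added. Against a count of 0 the floor was 3 counts per library. What a count of 0 is said to allow is set at 3 counts, or 3 cells for a share, and not at the exact limit. Genes with at least 5 CPM in either library were counted, 8704 in all, and a ratio of 1.5-fold marked those called higher. Where 2 identifiers shared a symbol (Aldoa, Ddit3), the identifier with more UMIs was used.

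The 30 gene lists, 21 marker lists, the filters and the size threshold were fixed before the data were examined. Each list was summarised by the median log2 ratio of its members with at least 5 CPM, and by that median's percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists outside the middle 95% are said to stand apart. The genes named in the text were drawn from a fixed set of T cell markers, the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in either library, and the up to 4 members of each list with the largest ratios in size, 136 genes in all. The rule of 12 left out mitochondrially encoded, ribosomal protein, predicted and antigen receptor segment genes. Other genes are named as cluster-leading genes, cell type markers, or genes said to be chosen after their values were seen.

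For shares of cells with a UMI, each cell was thinned without replacement to 2000 UMIs, which left out 133 NC and 94 HC cells. For clusters, counts were normalised to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 0.6 were used, with no batch correction because library and group are the same. A cluster was named from the fixed markers when at least 3 markers and at least 50% of those detected were raised. That naming threshold was set after the data were seen. A name was withheld where another list had more of its markers among the cluster's 10 leading genes. It was also withheld from a cluster far below the median depth that had no marker of the list among those genes. Cluster borders moved with the random start and with floating-point rounding, whose settings were held fixed. Ratios within clusters used those with at least 200 cells of each library.

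The summing, ratio and list steps were tested on simulated data, with counts drawn for the real genes at the real library sizes and 200 genes altered. Of 80 genes altered 2-fold and 80 altered 4-fold, 100% were called in the right direction, and of 40 altered by exactly 1.5-fold, 47.5%. Of 8404 unaltered genes 0 were called, and 93.4% of their intervals held the true ratio. Of 600 unaltered lists 4.67% fell outside the random range. Drawn counts carry no variation between animals or cultures, and each gene was drawn independently of the others. These figures thus say nothing of such variation, nor of lists whose genes move together.

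Alternatives to the scaling, cell weights, depth, cell filter, cells used, CPM floor, ratio size and clustering were run, some added after the data were seen. They included TMM factors from edgeR 4.0.16 and median-of-ratios size factors from DESeq2 1.42.0, used for scaling only. Gene positions came from GENCODE vM21 by identifier, which matched 32158 of 32285 identifiers (99.6%). Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3.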

Results

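Single-cell RNA libraries were made from mouse CD8+ T cells of lymph node origin, the lymphocytes that kill infected and malignant cells. The series compares such cells with and without electrical stimulation applied through the matrix, and asks how the stimulus relates to the fate the cells take. There were 2 libraries, labelled NC and HC, 1 in each group. The labels spell out neither abbreviation and do not say which library came from stimulated cells, so both are named by their labels. With 1 library per group there were no replicates: no test between the groups was possible, and every 95% interval below covers counting error only.

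The NC library held 14798 barcodes and 117408492 unique molecular identifiers (UMIs, tags that each mark 1 captured RNA molecule). The HC library held 15495 barcodes and 116897716 UMIs. After filtering, 13641 NC cells (92.2%) with a median of 6898 UMIs and 2032 genes were kept, and 13617 HC cells (87.9%) with a median of 7425 UMIs and 2176 genes. Barcodes with more than 10% of their UMIs from mitochondrially encoded genes, a sign of damaged cells, made up 7.41% of the NC library and 11.5% of the HC library. Summed over kept cells, 1 UMI weighed little: 115789139 NC and 114430972 HC UMIs entered the comparison, so a count of 0 allowed at most 0.0259 CPM (UMIs per 1000000 UMIs) in NC and 0.0262 CPM in HC.

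Most cells of both libraries carried CD8 transcripts. At least 1 UMI of Cd8a or Cd8b1, the chains of the CD8 co-receptor, with none of Cd4, was found in 98.4% of NC cells and 98.3% of HC cells. 1 UMI alone need not show expression. Unthinned Cd8a was also in 45% of the 20 NC cells of a B cell-like cluster (23.1 to 68.5) against 85.0% of the others. Igkc was in 65% of those 20 cells and doublets were not removed. They may thus not all be B cells, and the 45% cannot be read as background alone. Cd4, the co-receptor of helper T cells, had 1 UMI in NC and 2 UMIs in HC. Cd8b1 was at 568 CPM in NC (563 to 572) and 529 CPM in HC (525 to 533), and Cd3e, a signalling chain of the T cell receptor, at 341 CPM (337 to 344) and 308 CPM (305 to 311). Several markers of other cells were rare, though not all: Foxp3 of regulatory T cells had 3 and 2 UMIs, Ncr1 of natural killer cells 0 and 1, Csf1r of macrophages 2 and 1, and C1qa 0 in both, whereas Ikzf2, a further regulatory T cell marker, had 12390 and 9980 UMIs, Ighm of B cells 42783 and 52244, Trdc of gamma-delta T cells 14481 and 12151, and Pecam1 of endothelium 5049 and 4681. Cd79a of B cells had 176 UMIs in NC and 38 in HC. Igkc, the constant part of the antibody kappa chain, was 10.4-fold higher in NC (9.10 to 12) at 20.8 against 1.99 CPM, and 92.9% of its NC UMIs came from the 20 NC cells of the B cell-like cluster. Outside that cluster its log2 ratio of HC over NC was -1.87 (-2.37 to -1.39). Over 17 alternatives to the processing it came as near to 0 as -0.41, under 1.5-fold.

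Genes of low-oxygen metabolism and glycolysis were the most prominent group on the HC side, and chemokine genes on the NC side. Of 8704 genes with at least 5 CPM in either library, 168 were at least 1.5-fold higher in HC and 128 at least 1.5-fold higher in NC. The NC count was 65 without the cycling-like clusters and 67 without clusters 7 and 8, and the HC count was 111 without clusters 3, 6 and 9. The median log2 ratio of HC over NC across all of these genes was -0.03. Of 30 gene lists fixed before the data were examined, 7 had a median above and 7 a median below the middle 95% of 10000 random lists matched on expression, and 16 lay within it. The percentiles given below describe these libraries and do not test the conditions.

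**Figure D1:**
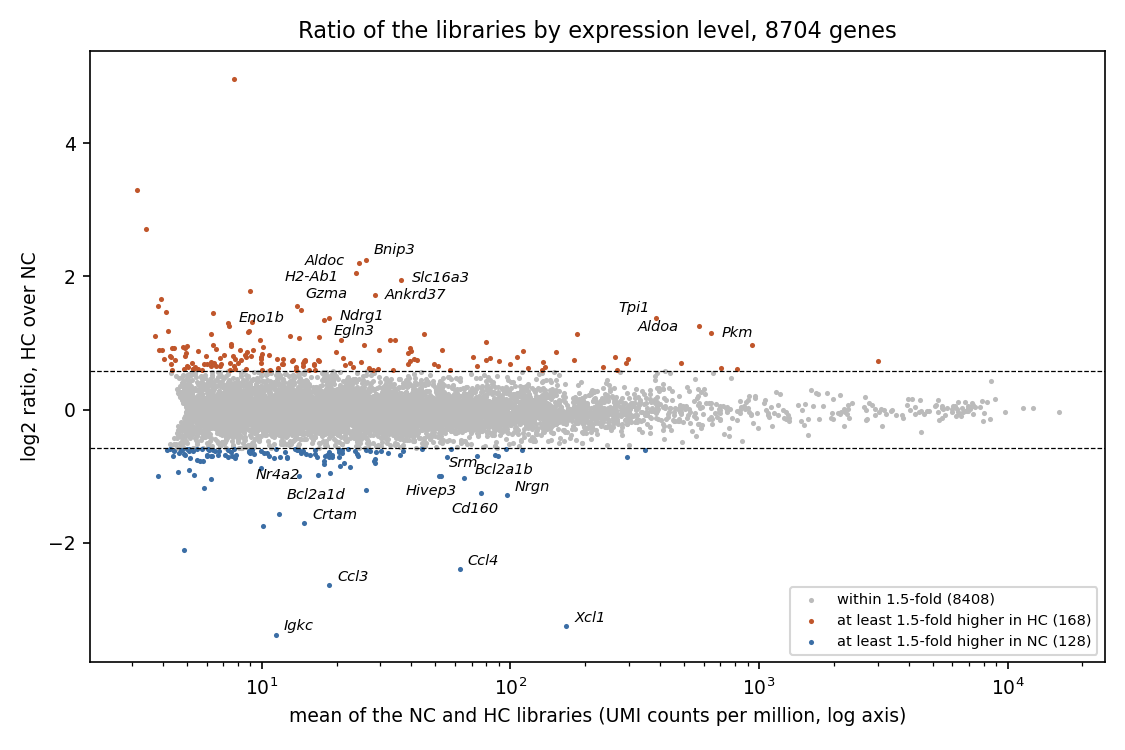
Log2 ratio of the HC over the NC library against the mean level in CPM (log axis), 1 point per gene, with dashed lines at 1.5-fold. The 168 genes past the upper line include Bnip3 at 2.25 and Tpi1 at 1.38, and the 128 past the lower line include Xcl1 at -3.26 and Ccl4 at -2.40.

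Genes that cells switch on in low oxygen were higher in the HC library. Bnip3, which directs mitochondria to degradation, stood at 9.11 CPM in NC (8.57 to 9.68) and 43.3 CPM in HC (42.1 to 44.5), 4.75-fold higher in HC. Ankrd37 was 3.31-fold higher in HC (3.12 to 3.51), Ndrg1 had a log2 ratio of 1.37 and Egln3, an oxygen-sensing hydroxylase that marks HIF proteins for destruction, 1.35. Of the 11 hypoxia genes measured, 9 were at least 1.5-fold higher in HC and 0 in NC, and the median log2 ratio was 0.97, above all 10000 random lists (percentile 100). Pdk1, a mitochondrial kinase that inhibits pyruvate dehydrogenase, was 2.07-fold higher in HC (1.97 to 2.17).

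Glycolysis, the breakdown of glucose to pyruvate and lactate, followed the same direction. Slc16a3, the lactate exporter MCT4, stood at 15 CPM in NC and 57.7 CPM in HC, 3.85-fold higher in HC (3.65 to 4.06). The glycolytic enzymes Tpi1 (214 against 557 CPM), Aldoa (338 against 805 CPM) and Pkm (401 against 888 CPM) were 2.60-fold, 2.38-fold and 2.22-fold higher in HC. Aldoc, a further aldolase outside the list, was 4.59-fold higher in HC (4.29 to 4.92), and Eno1b, an intronless copy whose reads may be shared with Eno1, had a log2 ratio of 1.5. Of the 17 glycolysis genes measured, 13 were at least 1.5-fold higher in HC and 0 in NC, with a median log2 ratio of 0.75 (percentile 100).

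Mitochondrial energy genes differed far less. The 13 mitochondrially encoded genes had a median log2 ratio of 0.11 (percentile 98.6), led by mt-Nd6 at 0.46, mt-Nd1 at 0.22, mt-Nd5 at 0.19 and mt-Co3 at 0.16. Nuclear genes of oxidative phosphorylation had a median of 0.03 over 28 genes (percentile 94.0), within the random range here but above it under 4 of 18 alternatives: Cycs, or cytochrome c, was at -0.32 and Atp5g1 at -0.20, while Cox6a1 was at 0.21 and Uqcrfs1 at 0.18. Fatty acid oxidation genes had a median of 0.06 (percentile 93.9), with Ppargc1b at -0.39, Cpt2 at 0.29, Hadh at 0.23 and Acadvl at 0.20. The mitochondrially encoded genes were measured beside a larger share of damaged barcodes in HC, and a stricter cell filter took their median to 0.07, within the random range.

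Proliferation and lipid synthesis genes were also higher in the HC library. The 34 genes of DNA replication and mitosis had a median log2 ratio of 0.26 (percentile 100), and 33 of them lay above 0, though 0 reached 1.5-fold. Mki67, a marker of dividing cells, stood at 357 CPM in NC (353 to 360) and 522 CPM in HC (518 to 526), Top2a, which untangles DNA, at 532 and 776 CPM, and Cdt1, a replication licensing factor, at 32.2 and 45.6 CPM. Ung, which removes uracil from DNA, was instead higher in NC, at a log2 ratio of -0.50. Genes of cholesterol and fatty acid synthesis had a median of 0.23 (percentile 100), with the desaturases Scd1 at 1.45 and Scd2 at 0.56 and the sterol pathway enzymes Fdps at 0.64 and Mvk at 0.46. Without the cycling-like clusters the median of the DNA replication list was -0.03.

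Secreted signals of activated T cells were higher in the NC library. Xcl1, a chemokine that attracts cross-presenting dendritic cells, stood at 304 CPM in NC (301 to 307) and 31.9 CPM in HC (30.8 to 32.9), 9.55-fold higher in NC. The inflammatory chemokines Ccl3 (32.1 against 5.16 CPM) and Ccl4 (105 against 19.9 CPM) were 6.21-fold and 5.28-fold higher in NC. Ifng, the interferon that activates macrophages, was 4.34-fold higher in NC (3.73 to 5.07) at 7.89 against 1.82 CPM. Without clusters 3, 7 and 8 the log2 ratio of Ifng was -0.41, under 1.5-fold, that of Ccl3 -0.89, of Ccl4 -1.04 and of Xcl1 -1.84. Of the 10 cytokine and chemokine genes measured, 6 were at least 1.5-fold higher in NC and 0 in HC, and the median log2 ratio was -0.78, below all random lists (percentile 0).

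Part of the genes of inhibition and of those that follow receptor engagement were also higher in the NC library. Among 8 genes of inhibition and exhaustion the median log2 ratio was -0.55 (percentile 0), with Cd160 at -1.25, Nr4a2 at -0.98, Nr4a3 at -0.98 and Tox, a factor that sets the exhausted state, at -0.78, while 2 of the 8 lay above 0, up to 0.41. Pdcd1, which encodes PD-1, stood at 34.5 CPM in NC (33.5 to 35.6) and 27.7 CPM in HC (26.8 to 28.7). Activation and co-stimulation genes had a median of -0.24 (percentile 0), with the early response factors Egr2 at -0.94, Nr4a1 at -0.65 and Egr3 at -0.61, and 8 of 20 genes above 0. Cd69, an early activation marker, had a log2 ratio of -0.13 and Cd44, a marker of antigen experience, of 0.02 with an interval that included 0. Il2ra, the high-affinity chain of the interleukin-2 receptor, was instead 1.67-fold higher in HC (1.60 to 1.74). Without clusters 7 and 8 the medians were -0.07 for the inhibitory and 0.01 for the activation list, and without clusters 3, 7 and 8 they were 0.12 and 0.04, all inside the random range. Within clusters Nr4a1 was higher in HC in 5 of 7, Egr2, Egr3 and Nr4a3 each in 4 of 7, and Nr4a2 in 2 of 7 (-0.30 to 0.13). Without clusters 3, 7 and 8 the log2 ratio of Nr4a2 was 0.29.

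Other genes at the NC end belonged to no single list. Crtam, an adhesion receptor of activated T cells, was 3.27-fold higher in NC (3.02 to 3.55), and Nrgn, a calmodulin-binding protein, had a log2 ratio of -1.29. Bcl2a1b and Bcl2a1d, survival factors at -1.03 and -1.22, are near-identical copies that the counting may not separate. Hivep3, a zinc finger protein, was at -1.0, and Srm, which makes spermidine, at -0.99. Without clusters 3, 7 and 8 Bcl2a1b and Hivep3 were both at -0.45 and Srm at -0.21, under 1.5-fold. The ratios nearest 0 over 17 alternatives were -0.82 for Crtam, -0.65 for Nrgn and -0.60 for Bcl2a1d, all still at least 1.5-fold.

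Genes of the T cell receptor pathway were lower in the HC library by small amounts. The list had a median of -0.17 (percentile 0.08) with 17 of 20 genes below 0 and 0 past 1.5-fold. Cd8a was 1.45-fold higher in NC (1.43 to 1.47), at 354 against 244 CPM, and the kinase Fyn (-0.39), the adaptor Lcp2 (-0.34) and the receptor chain Trac (-0.29) followed.

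Killing genes were split. The granzymes Gzma and Gzmb, proteases delivered into target cells, were 2.95-fold (2.72 to 3.19) and 1.69-fold (1.67 to 1.72) higher in HC, Gzmb at 373 against 221 CPM. Prf1, which encodes the pore that admits them, had a log2 ratio of -0.52, though it was higher in HC in 5 of 7 clusters (-0.50 to 0.35), and Serpinb9, an inhibitor of granzyme B, of -0.32. The cytotoxic list as a whole had a median of -0.17 (percentile 0.41), while its mean of 0.04 lay on the other side of 0. Effector transcription factors had a median of 0.10 (percentile 97.7), with Prdm1, which drives terminal differentiation, at 1.46, Nfil3 at 0.66, Batf3 at 0.60 and Bhlhe40 at 0.57; that median lay inside the random range under 7 of 18 alternatives.

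Naive and memory genes showed no common direction, with a median of 0.02 over 17 genes (percentile 85.1). Klf3, a repressor of transcription, had a log2 ratio of 0.45. Tcf7, the factor TCF-1 that preserves self-renewal, stood at 263 CPM in NC (260 to 266) and 219 CPM in HC (216 to 221). Id3 was at -0.71, Myb at -0.43 and Bach2 at -0.35. Il7r, the receptor for the survival cytokine interleukin-7, was the same within counting error at 247 CPM in both.

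Genes of ribosome assembly were higher in the NC library as a list, while those of nutrient uptake lay within the random range under the main processing. Genes of ribosome assembly and translation had a median log2 ratio of -0.47 (percentile 0) with 19 of 21 genes below 0 and 6 at least 1.5-fold higher in NC, among them Nop16 at -0.77, Rrp9 at -0.71, Nolc1 at -0.70 and Rrp12 at -0.64. Without clusters 3, 7 and 8 the median was -0.12, still below the random range, and Nop16 was at -0.25, Rrp9 at -0.19, Nolc1 at -0.15 and Rrp12 at -0.34, all under 1.5-fold. Amino acid uptake and mTORC1 genes lay within the random range at -0.08 (percentile 15.6), with Eif4e and Slc3a2 both at -0.46, Eif4ebp1 at 0.39 and Tsc2 at 0.36. At a floor of 20 CPM their median was -0.21, below the random range. Within clusters it was below 0 in 7 of 7 (-0.16 to -0.0077), and below the random range in 1. Stress genes of the endoplasmic reticulum were at -0.12 (percentile 2.76), with Asns at -0.71, Ddit3 at -0.51, Pdia4 at -0.38 and Pdia6 at -0.34. The median of that list lay within the random range here and under 14 of 18 alternatives, but below it in 4 of 7 clusters. The 8 heat shock genes were at -0.10 (percentile 9.68), with the chaperones Hspd1 at -0.54, Hsph1 at -0.44 and Dnaja1 at -0.29 lower in HC and Hsp90ab1 at 0.19. Apoptosis and p53 genes were at -0.09 (percentile 10.2), with the nuclease Aen at -0.82, Bid at -0.42 and Phlda3 at -0.35, against the cell cycle inhibitor Cdkn1a at 0.51.

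Calcium entry and NFAT genes had a median of 0.00284 over 25 genes (percentile 82.4), with the calcium pumps Atp2b4 at 0.46, Atp2a3 at 0.33 and Atp2a2 at -0.32 and the calcium release channel Itpr3 at 0.42. Ion channels and pumps were at 0.04 (percentile 88.5), but above the random range under 5 of 18 alternatives, at 0.17 with cells thinned (percentile 99.3), and in 3 of 7 clusters. They were led by the calcium channel subunit Cacna1s at 0.66 and the chloride exchanger Clcn3 at 0.52, with P2rx4 at -0.37 and Slc12a2 at -0.32. Immediate early genes were at -0.08 (percentile 18.3), with Ier3 at 0.51 and Dusp5 at 0.35 against Dusp2 at -0.50 and Dusp6 at -0.30. Adhesion and migration genes were at 0.10 (percentile 99.8) and mixed: the chemokine receptor Cxcr4 was at 0.79, the filament protein Vim at 0.70 and Vcl at 0.52, whereas Itgae, the integrin that binds epithelium, was 1.93-fold higher in NC (1.81 to 2.05). That median was -0.06 when only genes with at least 20 CPM were used.

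Interferon-stimulated genes had a median of -0.17 (percentile 0.47), with Ifi213 at -0.71, Isg20 at -0.59, Isg15 at -0.59 and Ifi206 at -0.44, and the interferon-gamma response list was at -0.10 (percentile 4.68), with the GTPases Irgm1 at -0.54, Iigp1 at -0.51 and Gbp6 at -0.38 against Gbp7 at 0.37. The latter list lay below the random range under 4 of 18 alternatives. Within clusters, however, its median ran from -0.23 to 0.20 and was above 0 in 5 of 7. It lay above the random range in 3 clusters and below it in 1. Genes of the common gamma-chain and JAK-STAT pathway were at 0.05 (percentile 95), with the feedback inhibitor Socs2 at 1.56 and the kinase Pim1 at 0.75 against the receptor Il15ra at -0.55. PI3K and FOXO genes were at -0.00025 (percentile 74.7, with Pdk1, which acts on pyruvate dehydrogenase and not in that pathway, counted at 1.05), with Klf2 at 0.28 against Btg1 at -0.61 and Txnip at -0.31. TGF-beta genes were at -0.03 (percentile 50.1), with Tgif1 at -0.38, Smad2 at -0.23 and Ski at -0.17, and Notch and Wnt genes were at -0.05 (percentile 40), with Notch2 at -0.56, Notch1 at -0.09 and Tle1 at 0.17. Without clusters 3, 7 and 8 the Notch and Wnt median was -0.18, below the random range. At a floor of 20 CPM the interferon-stimulated median was -0.02.

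**Figure D2:**
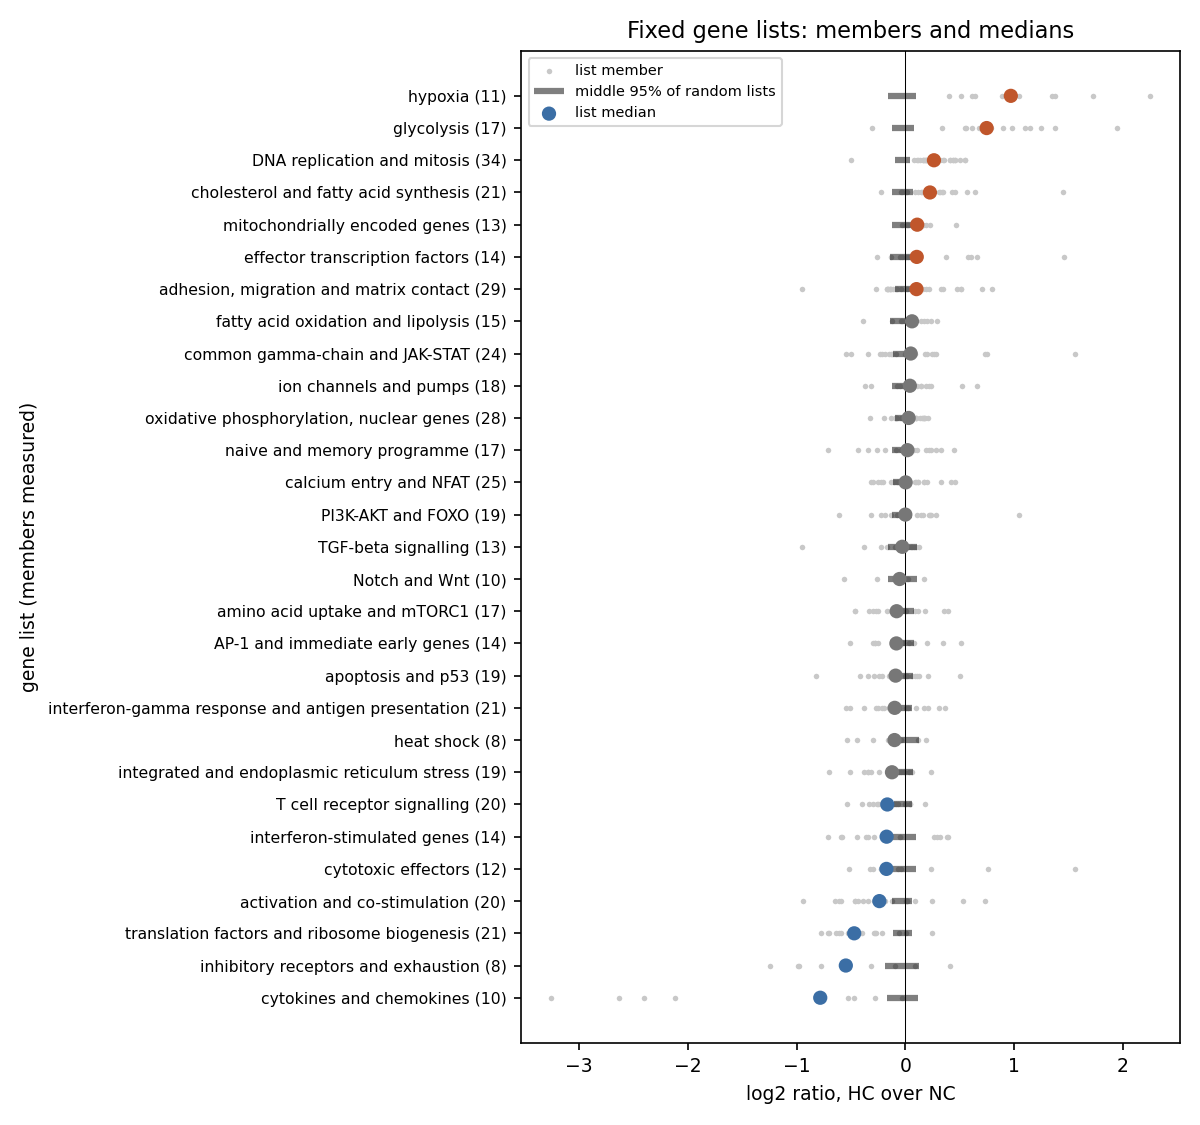
Log2 ratio of HC over NC for the members (small points) and the median (large point) of each list shown, with bars for the middle 95% of the random lists. Orange medians lay above that range, from hypoxia at 0.97 to adhesion at 0.10, and blue medians below it, down to cytokines and chemokines at -0.78.

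The shares of cells with a UMI, taken after thinning each cell to 2000 UMIs, followed the summed counts. Mki67 was found in 31.9% of NC cells (31.1 to 32.7) and 46.8% of HC cells (45.9 to 47.6), and Gzmb in 24.1% (23.3 to 24.8) and 35.8% (35.0 to 36.6). Cd8a was found in 48.9% (48.0 to 49.7) and 37.7% (36.9 to 38.6), and Tcf7 in 40.2% and 36.3%. Il7r (38.6% and 38.4%), Cd44 (5.66% and 5.92%) and Cd69 (10.1% and 9.68%) differed by less than counting error at this depth. Cd44 was higher in HC by 0.56 points (0.15 to 0.96) at 1000 UMIs and 0.98 (0.19 to 1.76) at 4000. Unthinned, HC minus NC was 1.42 points for Cd44 (0.45 to 2.39) and -1.16 for Cd69 (-2.24 to -0.08). Ifng was rare at 0.814% and 0.266%, Pdcd1 was in 5.86% and 4.98%, Il2ra in 5.06% and 7.98%, and Cd4 in 1 NC cell and 0 HC cells, where a count of 0 allows up to 0.0222%. Thinning left out 133 NC and 94 HC cells; unthinned, Mki67 was in 53.4% and 69.2%, Gzmb in 49.7% and 64.6%, Cd8a in 84.9% and 78.6% and Il7r in 72.3% and 74.8%. In the B cell-like cluster (19 NC cells deep enough, median depth before thinning 11016 UMIs in NC and 2958 in HC), Cd8a, which B cells lack, was in 31.6% of NC cells (12.6 to 56.6), Tcf7 in 26.3% (9.15 to 51.2), Gzmb in 10.5% (1.30 to 33.1), and Ifng in 0, which allows up to 15.8%. The cells are too few to set a background for the rarer genes, and Mki67, Il2ra, Cd44 and Il7r can be expressed by B cells as well. Igkc was in 68.4% of the 19 NC cells and doublets were not removed, so these cells may not all be B cells.

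**Figure D3:**
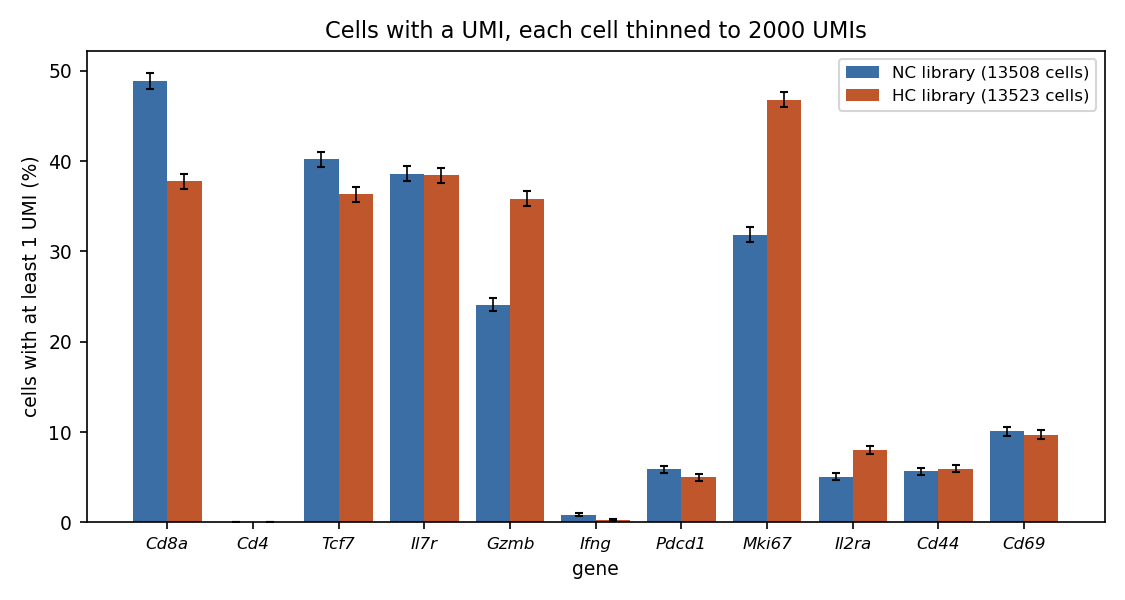
Share of cells with at least 1 UMI of each gene after thinning to 2000 UMIs, in the NC (blue, 13508 cells) and HC (orange, 13523 cells) libraries, with exact binomial 95% intervals for counting error. The widest gaps are those of Mki67, at 31.9% against 46.8%, and Gzmb, at 24.1% against 35.8%.

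Clustering both libraries together gave 11 clusters. Cluster 1 was naive or resting T-like, though interferon-inducible genes (Iigp1, Ifi213, Ifi206) were among its leading genes. Cluster 2 was cycling-like, and so was cluster 6, whose leading genes were however those of hypoxia and glycolysis (Bnip3, Slc16a3, Ankrd37, Tpi1). Clusters 7 and 8 were recently activated T-like and led by Ccl4, Xcl1 and Ccl3, and cluster 11, with 26 cells, was B cell-like. Clusters 3, 4, 5, 9 and 10 stayed unnamed: cluster 3 was led by Rpgrip1, Slc39a1, Xcl1, Ccl4 and Ccl3, cluster 4 by S-phase genes (Ung, Cdc6, Mcm2), cluster 5 by sterol synthesis genes (Hmgcs1, Idi1, Cyp51) and cluster 9 by Mgarp, Aldoc and Bnip3. Cluster 3 came to 92.9% from NC, and clusters 6 and 9 came to 95.1% and 99.9% from HC, so each may mark its library and not a cell type.

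Cells in the cycling-like class were more frequent in the HC library. Because the differing genes shaped the clusters, the class was taken from a clustering without the 108 of 2000 variable genes that were at least 1.5-fold apart. It then held 20.9% of NC cells (20.2 to 21.6) and 42.7% of HC cells (41.8 to 43.5). An unnamed cluster led by S-phase genes in that clustering, kept out of the class by a naming threshold set after the data were seen, held a further 8.41% of NC and 13.8% of HC cells. With all variable genes the class held 13.8% (13.2 to 14.4) and 37.8% (37.0 to 38.6): cluster 2 supplied 1797 NC and 3475 HC cells and cluster 6 supplied 86 NC and 1675 HC cells.

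The differences in hypoxia, glycolysis, chemokine and ribosome biogenesis lists were also found in each of the clusters compared, and others in some or none. In each of the 7 clusters with at least 200 cells of each library, the hypoxia median (0.45 to 0.89) and the glycolysis median (0.39 to 0.66) lay above the random range, and the cytokine and chemokine median (-0.69 to -0.27) and the ribosome biogenesis median (-0.41 to -0.17) below it. Bnip3 was higher in HC in 7 of 7 clusters, at log2 ratios of 0.84 to 1.87, Gzmb in 7 of 7 at 0.33 to 0.77, and Xcl1 was higher in NC in 7 of 7 at -2.68 to -1.27. Ifng and Ccl4 were each higher in NC in 6 of 7 and higher in HC in 1, at 0.99 and 0.28. Cholesterol and fatty acid synthesis medians ran from -0.14 to 0.33 and were above 0 in 4 of 7, and T cell receptor medians (-0.14 to -0.05) were outside the random range in 0 of 7. Effector transcription factors and mitochondrially encoded genes each lay above it in 5 of 7, the latter also below it in 1. DNA replication genes were higher in HC in cluster 1, at a median of 0.34, and in cluster 3, at 0.07, both above the random range, and lay within it in the other 5 clusters. The inhibitory receptor medians ran from -0.11 to 0.15 and none lay below the random range. Interferon-stimulated genes were lower in HC in cluster 1, at -0.31, and higher in clusters 7 and 8, at 0.26 and 0.42. The clusters were formed on genes that include those compared, which narrows differences within them. Cluster 3, with 237 HC against 3117 NC cells, may mark its library, so its comparison may not be of like cells. Free RNA, weighed below, could give the same sign in every cluster.

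**Figure D4:**
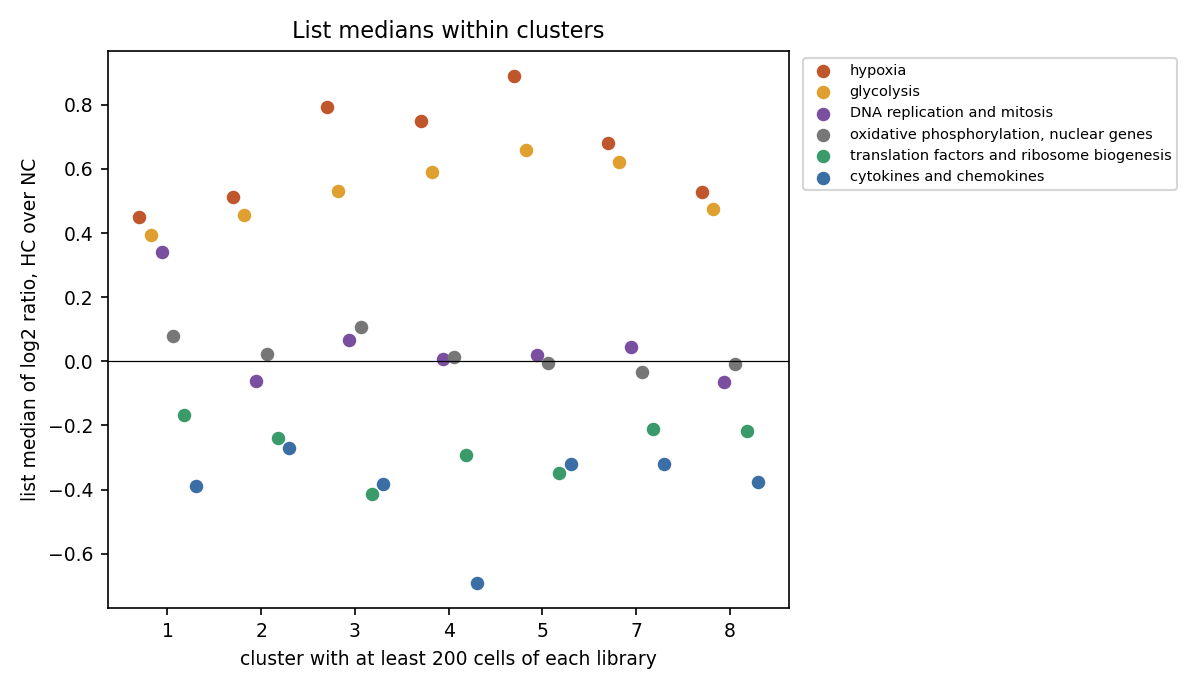
Median log2 ratio of HC over NC for 6 gene lists within each of the 7 clusters with at least 200 cells of each library, 1 point per list and cluster. The hypoxia points lie between 0.45 and 0.89 and the cytokine and chemokine points between -0.69 and -0.27.

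By gene identifier in GENCODE vM21 (GRCm38, the assembly called mm10), Bnip3 (ENSMUSG00000078566) is a protein-coding gene on chromosome 7 from 138890836 to 138909519, minus strand, and Aldoa (ENSMUSG00000030695) lies on the same chromosome from 126795234 to 126800751. Slc16a3 (ENSMUSG00000025161) lies on chromosome 11 from 120948480 to 120960868, plus strand, and Tpi1 (ENSMUSG00000023456) on chromosome 6 from 124810586 to 124814296. Ccl3 (ENSMUSG00000000982) and Ccl4 (ENSMUSG00000018930) are neighbours on chromosome 11, from 83647844 to 83649355 and from 83662584 to 83664683, and Xcl1 (ENSMUSG00000026573) lies on chromosome 1 from 164931644 to 164935527. Gzmb (ENSMUSG00000015437) lies on chromosome 14 from 56258838 to 56262260. Counts are per gene and do not resolve exons; 33 of the 136 genes chosen by rule share a strand and position with another annotated gene, among them Pkm, Ifng, Il2ra, Cd3e and Tcf7, so some of their UMIs may belong to it.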

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

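Of the tests below, the one that thins every cell was chosen before its result was seen, and all others were chosen after. With 1 library per group no check for outlying samples was possible.

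Hypoxia and glycolysis genes were higher in the HC library, with a median log2 ratio of 0.97 for the hypoxia list. Without clusters 6 and 9, which those genes led, the median was 0.66, which argues against those cells alone as the whole cause. With every cell thinned to 2000 UMIs, so that deep cells weighed no more than others, the median was 0.98. That argues against the weight of deep cells as the whole cause. Ratios were already scaled to each library's total, so thinning could not test depth per cell itself. Free RNA from clusters 6 and 9 stays open for the excess in the remaining cells. Over 9 hypoxia genes that excess differed between clusters by a median factor of 1.04 after counting error. The factor was 0.782 at resolution 1.0, but 3.56 under another random start, where 1 cluster and not 2 was the source. For each gene it is a lower limit, the smaller of those in CPM and in UMIs per cell, so the excess itself can differ more. For Pdk1, the gene at 1.04, the excess ran from 11.6 to 27.8 CPM. A difference between the cells of the 2 libraries in oxygen, cell density or handling, and the electrical stimulus itself, may each account for the pattern, and neither was tested since each group is 1 library.

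Chemokine and cytokine genes were higher in the NC library, with a list median of -0.78. Without clusters 7 and 8 it was -0.65. Without cluster 3 as well, which also had Xcl1, Ccl3 and Ccl4 among its leading genes, it was -0.63. That argues against those cells alone as the whole cause of the list median. The genes furthest apart moved much more: without clusters 3, 7 and 8 Ifng went from -2.12 to -0.41 and Ccl3 from -2.63 to -0.89. Ccl4 went from -2.40 to -1.04 and Xcl1 from -3.26 to -1.84. Free RNA from clusters 7 and 8 cannot be told apart from other causes. The excess differed between the other clusters by a median factor of 7.46 over 6 genes, but that is the midpoint of 0.915 and 14. Of the 6, 3 were below 1 and 3 at 2 or more: Xcl1 at 14, and Ifng and Ccl4, whose NC excess was negative in cluster 3 beyond counting error. Cluster 3 was the highest or the lowest cluster for each of the 6 genes. It came to 92.9% from NC and was led in part by these genes, so the test decides nothing for them. A different time since antigen receptor engagement and the electrical stimulus stay open as possible explanations and were not tested.

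H2-Ab1, a chain of the class II molecule that presents antigen to helper T cells, was 4.16-fold higher in the HC library (3.89 to 4.45) at 38.5 against 9.26 CPM, and higher in HC in 7 of 7 clusters. RNA of B cell-like or other antigen-presenting cells would bring the partner genes H2-Aa, Cd74 and H2-Eb1, yet in HC cells outside the B cell-like cluster these had 4, 471 and 185 UMIs, at most 3.59% of the number needed. That argues against such cells as the source. H2-Ab1 was also among the 10 leading genes of clusters 6 and 9, which came to 95.1% and 99.9% from HC. Free RNA from those clusters was not tested for H2-Ab1 and stays open. Transcription of H2-Ab1 in the T cells themselves stays open as a hypothesis, and no biological explanation was tested.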

How the results depend on the processing

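Alternatives that leave out numbered clusters or the highest doublet scores, and the other random start and the clustering without differing genes, were chosen after seeing the data. The medians of hypoxia (0.62 to 1.07), glycolysis (0.49 to 0.98), cholesterol and fatty acid synthesis (0.14 to 0.30), cytokines and chemokines (-1.33 to -0.62), ribosome biogenesis (-0.47 to -0.12) and T cell receptor signalling (-0.19 to -0.15) kept their direction and stayed outside the random range in all 18 alternatives. Of 55 named genes at least 1.5-fold apart, 51 kept their direction in all of 17 alternatives, and 29 stayed at least 1.5-fold apart. The floors of 1 and 20 CPM leave a gene's ratio unchanged, and the changes of scaling shift all ratios alike, so these say little of single genes. The changes of scaling also shift a list and its random lists alike. They could move a list's percentile only through genes that crossed the floor, so they say little of lists either. The exceptions in direction were Nr4a1, at 0.016 without clusters 7 and 8 and 0.65 without clusters 3, 7 and 8, and under the latter Nr4a2 at 0.29, Egr2 at 0.10 and Egr3 at 0.30. No scaling shifted all genes by more than 0.015 log2 units. No paired analysis was possible because each group is 1 library. Leaving out called doublets, chosen before the data were examined, was not done, since none was called. Each list median below is of a list that crossed the limits of the random range: effector transcription factors, adhesion, activation, inhibitory receptors, cytotoxic effectors, interferon-stimulated genes, mitochondrially encoded genes and DNA replication then lay inside it, and all other lists outside it. The cause was not tested unless it is named.

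With cells thinned to 2000 UMIs the medians were 0.079 for effector transcription factors, 0.17 for ion channels and pumps, 0.12 for fatty acid oxidation, -0.18 for endoplasmic reticulum stress and -0.14 for the interferon-gamma response. With equal weight per cell they were 0.075 for effector transcription factors and -0.14 for the interferon-gamma response, and with a total that left out mitochondrial, ribosomal protein and the 50 most abundant genes 0.12 for ion channels. The stricter cell filter gave 0.019 for adhesion, 0.073 for mitochondrially encoded genes and 0.066 for oxidative phosphorylation.

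A floor of 1 CPM gave 373 genes at least 1.5-fold higher in HC and 248 in NC, with medians of 0.083 for effector transcription factors and 0.12 for ion channels. A floor of 20 CPM gave 69 and 56 genes, with medians of 0.021 for effector transcription factors, -0.21 for amino acid uptake and mTORC1, -0.13 for activation, -0.016 for interferon-stimulated genes and -0.060, on the other side of 0, for adhesion. At 2-fold, 38 genes were higher in HC and 16 in NC. Taking the mean over members gave 0.043, on the other side of 0, for cytotoxic effectors, 0.076 for adhesion, -0.13 for interferon-stimulated genes, -0.15 for heat shock, -0.18 for endoplasmic reticulum stress and 0.14 for mitochondrially encoded genes.

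Without the cycling-like clusters 65 genes were at least 1.5-fold higher in NC, and the medians were 0.052 for PI3K and FOXO, 0.10 for the naive and memory programme, 0.028 for oxidative phosphorylation, 0.082 for fatty acid oxidation and, since part of the dividing cells were removed, -0.030 for DNA replication and mitosis. Without clusters 6 and 9 they were 0.036 for effector transcription factors, 0.093 for ion channels, -0.13 for endoplasmic reticulum stress and 0.084 for the common gamma-chain. Without clusters 7 and 8, 67 genes were higher in NC, and the medians were -0.065 for inhibitory receptors, 0.0088 for activation, -0.00059 for adhesion and -0.18 for the interferon-gamma response. Without clusters 3, 7 and 8, 80 genes were higher in NC, and the medians were 0.040 for activation, 0.12 for inhibitory receptors, -0.065 for adhesion, -0.039 for cytotoxic effectors, 0.065 for effector transcription factors, 0.079 for mitochondrially encoded genes, 0.084 for oxidative phosphorylation, -0.16 for the naive and memory programme, -0.18 for Notch and Wnt and -0.25 for the interferon-gamma response. Without clusters 3, 6 and 9, 111 genes were higher in HC, and the medians were -0.0038 for effector transcription factors, 0.095 for ion channels and 0.046 for oxidative phosphorylation.

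Without the 10% of cells with the highest doublet score the median of endoplasmic reticulum stress was -0.13, and the share of cycling-like cells was 22.2 points higher in HC. Clustering without the genes at least 1.5-fold apart gave 21.7 points, against 24.0 with them.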

Other observations

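The genes in this part were chosen after their values were seen, and the values carry no test.

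Further genes, most of them under the level used for naming, followed the metabolic difference or lay apart from it. Mgarp, a mitochondrial protein induced in low oxygen, stood at 0.475 CPM in NC (0.358 to 0.618) and 14.9 CPM in HC (14.2 to 15.7), a log2 ratio of 4.97. Pygl, a glycogen phosphorylase that frees glucose from glycogen, had a log2 ratio of 3.30 at 5.70 CPM in HC, and the glucose transporters Slc2a1 and Slc2a3 had ratios of 1.10 and 0.75. Ifitm1, an interferon-inducible membrane protein, was at 1.79. Of the 14 interferon-stimulated genes measured, 9 lay below 0 in the summed counts and 5 above, while within clusters the list median was above 0 in 5 of 7. On the NC side Rgs16, which shortens chemokine receptor signals, stood at 17.6 CPM against 5.92 CPM in HC. Hif1a itself, the oxygen-sensitive factor, had a log2 ratio of 0.14.

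Constant-region genes of other lymphocytes were found throughout the CD8+ T cells. Ighm, the constant part of the antibody mu chain, stood at 363 CPM in NC and 456 CPM in HC outside the B cell-like cluster, and ran from 230 to 567 CPM across the large clusters and libraries, while Cd79a, which B cells need to carry that chain, stood at 0.234 and 0.140 CPM. Trdc, the constant part of the delta chain of gamma-delta T cells, stood at 125 CPM in NC and 106 CPM in HC and ran from 79.7 to 160 CPM across the large clusters, with Tcrg-C1 at 42 and 49 UMIs in all. Lyz2, a lysozyme of myeloid cells, had 416 UMIs in NC, 180 of them in the 20 NC cells of the B cell-like cluster and 227 in cluster 7, and 0 UMIs in HC, which allows up to 0.0262 CPM.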
